A study of Aspergillus niger with 6 samples.

How the data were processed

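Total RNA from mycelium of Aspergillus niger N402 was compared on 6 Agilent 2-colour arrays. Per the labels' protocols, cultures grew at 30 °C in minimal medium with fructose, mycelium was then transferred to xylan, and 5 µg of RNA entered each labelling, with Cy5 for xylan samples and Cy3 for the fructose control. The labels name 2 biological replicates at each of 3 times. They do not say whether the fructose RNA on different arrays came from 1 culture or several.

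The spot intensities were made by the authors with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes; per the file headers the slides were read on a GenePix scanner, and the mean pixel intensity and the local background of each spot were deposited without normalization. The processed intensities were background-subtracted with spatial detrending and dye-normalized within each array before they were deposited, per the file headers. The log10 ratio of each spot, Cy5 over Cy3, was computed from these processed signals before it was deposited, per the file headers. It equalled their ratio within 0.001 for 87.5% to 92% of spots. The authors also deposited a table of log2 values, 14110 per array, with steps not given in the sources used here. Set against the scanner log2 ratios, each of its columns had a slope between -1.01 and -1.00, so its scale is log2 and its direction fructose over xylan; how it was centred stays unknown. Its column medians were -0.08 and -0.02 at 6 h, -0.11 and -0.10 at 12 h, and 0.00 and 0.03 at 24 h. The other flags used, for signal above background, saturation and outlier spots, were taken as deposited.

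Each array held 44173 spots, of which 1417 were controls. The 14052 gene probes, 1 per gene, were spotted 3 times (13992 probes) or 13 times (60). Mean signals were corrected with normexp (offset 50) and normalized within each array by loess, with weight 0 for control and outlier-flagged spots (4.71% to 5.19% of spots), in limma 3.58.1 under R 4.3.3. The remaining spots of a probe were averaged. A probe was taken as above background or saturated where at least 0.5 of its spots were. 24 probes shared their sequence with another probe. Where a probe was not well above background, or saturated, on every array of a group, only a bound is given against fructose, as "at least N-fold". It sets the brighter group's mean against the higher of the dim probe's own signal and the lowest signal above background on each array, per channel after loess and Aquantile scaling, and is open to dye bias. Between times the bound is one of the Cy5 signal alone and none of the difference of ratios, which it can exceed. The difference of ratios of such a probe is printed as well and is inexact.

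Gene identifiers were those of the array. Of these, 13925 matched a locus of the RefSeq gene table of assembly ASM285v2 and 127 did not. The table gave a symbol for 127 genes on the array and no product text, so symbols cover a small part of the genes. Coordinates are not printed, because the array's build is not given in the sources used here.

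Log2 ratios were fitted in limma with a mean for each time over all 6 arrays, which share 1 estimate of the spread with 3 residual degrees of freedom and 1.44 from the empirical Bayes prior. Each mean was tested against 0 and each pair of times by its difference. Adjusted p values are Benjamini-Hochberg values over all genes tested, and a gene was called under 0.05. Where only SD is given, it is the SD of the replicate arrays; SE is that of the limma fit. Before the data were examined, gene lists by locus, the tests and the alternatives were fixed. Of 88 list loci 87 were on the array, and 39 of these have no symbol in the table and are given by locus with the function entered in the list. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 15 lists of a comparison with at least 3 measured genes. The 3 smaller lists (mannan, mannitol and sugar transport) were not tested, and 8 lists defined by words in product text were not analysed here, nor were word members of the other lists. Camera calls were set beside camera with an estimated correlation, with which no list was called in any comparison, and beside fry. With an estimated correlation camera tests on the 3 residual degrees of freedom, so a lost call does not show that correlation between genes made it. The pectinases at 6 h, with an estimated correlation of 0.0193, still went from an adjusted p of 0.00463 to 0.477 in camera.

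Genes named were, for each time against fructose, the 10 with the largest ratio each way among those called, with the same sign on both arrays and a symbol, and for each pair of times the 6 each way; all list loci also counted. Genes without a symbol that were larger than the last named gene were passed over, 31 and 729 higher and lower at 6 h, 26 and 958 at 12 h and 15 and 412 at 24 h. Alternatives were other background corrections and normalizations, the deposited ratios and table, a filter on dim probes, the replicate number as a block, slide as a random block, array weights, a trend and robust prior, a fit to the groups compared, and each array left out in turn. Both 6 h arrays left out, and the Cy5 signal alone, were added after seeing the data. The 6 h arrays lay on slides 1 and 2 of scan 1, and all 12 h and 24 h arrays on slide 3 of scan 2.

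The procedure was tested on simulated data with 200 changed genes among 13974. For 24 h against fructose 73% of changes of 1 on the log2 scale and 94% of changes of 3 were recovered, with 12 unchanged genes called. For 12 h against 6 h the shares were 45% and 86%, with 7 unchanged genes called. Of simulated lists of 9 genes, 100 of 100 shifted and 5 of 200 unshifted lists were called at 24 h. Simulated genes were independent, and each had the same spread on all 6 arrays. In the data the xylan hydrolases had an estimated correlation of 0.794, and array weights were 0.364 at 6 h and 2.13 at 12 h. The simulated shares therefore do not give the error rates of these data.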

Results

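RNA of Aspergillus niger N402, a laboratory wild-type strain of a filamentous fungus used to make enzymes and organic acids, was measured on 6 2-colour arrays. Mycelium was grown on fructose for 24 h and moved to 1% xylan, a plant polymer with a backbone of xylose, for 6, 12 or 24 h. Each time had 2 biological replicates, each on 1 array. Xylan RNA carried Cy5 and RNA of the fructose-grown control carried Cy3 on every array, so no array held the dyes the other way round. Per the labels the fructose control was one of 24 h on every array. No control followed the xylan times, so carbon source, transfer and culture age cannot be told apart in the ratios. Every value below is log2 of xylan over fructose, the direction the dyes give; the authors' deposited value table runs the opposite way. Between 70.3% and 77.5% of the 14052 genes were well above background in Cy5, and 76.4% to 85.5% in Cy3. The number of arrays limits the precision. Over genes, the log2 ratios of the replicate arrays correlated at 0.42 at 6 h, 0.90 at 12 h and 0.96 at 24 h, and genes are not independent replicates.

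**Figure D1:**
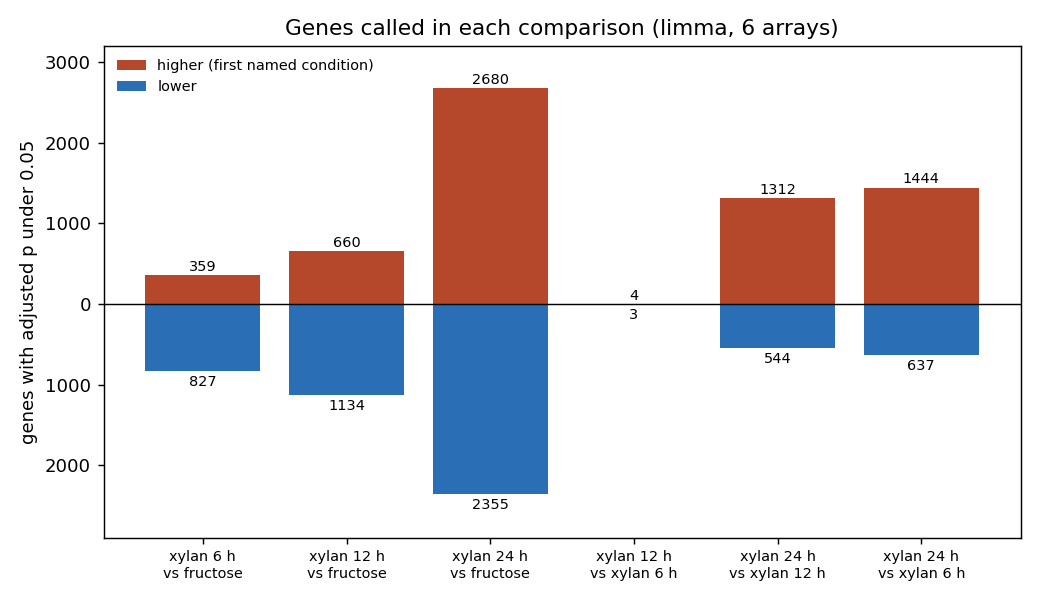
Bars give the number of genes with adjusted p under 0.05 that were higher (above 0) or lower (below 0) in the first named condition of each comparison, on the vertical axis. The 24 h comparison with fructose had 2680 higher and 2355 lower genes, and the 12 h comparison with 6 h had 4 and 3.

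The first question was which genes differed from the fructose control after 6 h on xylan. Each mean ratio was tested against 0, with the control as a fixed reference. This leaves out dye bias and any spread of the control that both arrays share. Whether the 2 arrays held the same fructose RNA is not given in the labels. The SE and p values use the spread of all 6 arrays and do not measure that of the 6 h replicates alone. A fit to the 6 h arrays alone called 0 genes. Genes for xylan breakdown and for use of its sugars were higher. The xylose reductase gene xyrA, whose enzyme opens pentose catabolism, had a log2 ratio of 7.29 ± 0.52 (SD, n = 2), with an SE of 0.19 and an adjusted p of 0.00279 in limma. The arabinofuranosidase gene abfB rose by 6.76 (SE 0.69, adjusted p = 0.016), the alpha-glucuronidase gene aguA by 6.15 (SE 0.27, adjusted p = 0.00447) and the beta-xylosidase gene xlnD by 4.53 (SE 0.13, adjusted p = 0.00279). Of the 9 xylan hydrolase genes fixed in advance, 4 were called higher and none lower, and 8 were called higher when adjusted over the list alone (camera adjusted p = 1.75e-05, and adjusted p = 0.477 with an estimated correlation). Besides xlnD and aguA these were aceA (5.37), entered in the list as acetyl xylan esterase, and the endoxylanase gene xynB (5.23). The 6 h replicates lay apart here too: the list's median was 1.73 in replicate 1 and 5.27 in replicate 2. The gene xynB was at 3.50 and 6.96. The uncalled axhA, xynA (An03g00940) and An15g04550 were at 1.23 and 5.04, 0.88 and 5.27, and 0.67 and 4.19. Replicate values were 5.44 and 8.09 for abfB, 4.67 and 6.08 for aceA, and 5.62 and 6.68 for aguA. The pentose catabolism list had 4 of 4 genes called higher, and 4 when adjusted over the list alone (camera adjusted p = 0.000107, and adjusted p = 0.477 with an estimated correlation). The list's median was 2.99 and 4.94 on the replicate arrays, and its other members were An12g00030 (4.25), An07g03140 (3.68) and An01g10920 (2.61), entered in the list as genes for xylitol dehydrogenase, xylulokinase and arabitol dehydrogenase.

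In the list of enzymes that release arabinose and galactose, 4 of 7 genes were called higher, and 4 when adjusted over the list alone (camera adjusted p = 0.000401, and adjusted p = 0.526 with an estimated correlation), among them abfA (3.34) and the beta-galactosidase gene lacA+ (3.40). Of 12 pectinase genes, 3 were called higher and 4 when adjusted over the list alone, with pelA at 2.28 and pmeA at 1.36 (camera adjusted p = 0.00463, and adjusted p = 0.477 with an estimated correlation). Of 5 genes of gluconeogenesis and the glyoxylate cycle, 2 were called higher and 4 when adjusted over the list alone (camera adjusted p = 0.00463, and adjusted p = 0.477 with an estimated correlation). An01g09270, entered as isocitrate lyase, was at 2.58 and An04g05300, entered as fructose-1,6-bisphosphatase, at 0.89. The sugar transporter locus An12g07450 was higher by 1.56 and the mannitol locus An03g02430 fell by 1.92 on the log2 scale. The 4 genes with a symbol that fell were the acid phosphatase gene aphA (-1.62), the tannase gene Tan1 (-1.17), nsfA (-0.66) and goxC (-0.42). Larger falls without a symbol, An13g02990 (-3.87) and An07g00580 (-3.73), were picked after their values were seen.

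Cellulase genes lay apart on the 6 h arrays. The cellobiohydrolase gene cbhB was at -0.14 in replicate 1 and 6.56 in replicate 2, and cbhA was at -0.00 and 4.74. The endoglucanase gene eglA was at 2.23 and 6.24, and the feruloyl esterase gene faeA at 1.73 and 6.11; none of these passed the test at 6 h. Of 7 cellulase and beta-glucosidase genes, 1, the beta-glucosidase gene bgl1 at 4.18, was called, and 2 when adjusted over the list alone (camera adjusted p = 0.00536, and adjusted p = 0.572 with an estimated correlation). The cellulase list's median was 0.20 in replicate 1 and 4.74 in replicate 2. In the same order, medians were 0.64 and 0.02 for the pentose phosphate list and 0.29 and 0.38 for the regulators. Those of the starch and secretory stress lists were 0.22 and 2.08, and 0.00 and 1.34. Glycolysis had 1.02 and -1.04, and so changed direction. Without 1 of these arrays the 6 h group is a single array, so a list test then holds no spread between the 6 h replicates.

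Counts below without a 6 h array rest on 1 array at 6 h and hold no spread between the 6 h replicates. In all, 1186 of 14051 genes were called at 6 h, 359 higher and 827 lower, and 423 of them changed at least 2-fold. This count used the spread of all 6 arrays: a fit to the 6 h arrays alone called 0 genes, array weights 109 and slide as a random block 405, and 3716 genes had an unadjusted p under 0.05. Without 6 h replicate 1 the count was 3993, without either 12 h array 170, and without either 24 h array 258; the higher share was 30.3%, 21.5% with median centring, 22% with slide as a random block and 41.4% with the authors' table. It was 49.4% without 6 h replicate 1, 39.8% without 6 h replicate 2, 19.4% without either 12 h array, 23.6% without either 24 h array and 18.3% with array weights.

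**Figure D2:**
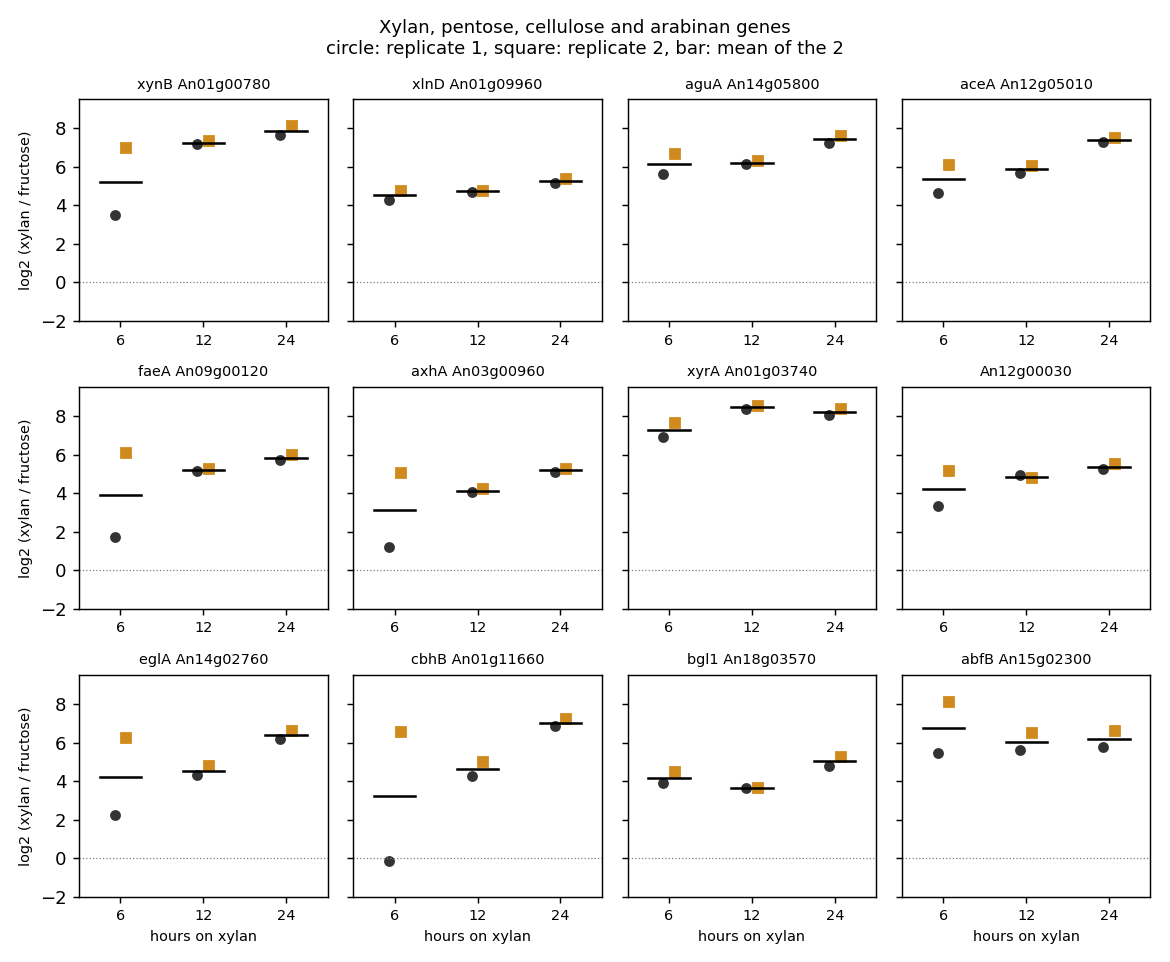
Each panel shows 1 gene, with hours on xylan on the horizontal axis and log2 of xylan over fructose on the vertical axis; circles are replicate 1, squares replicate 2 and bars the mean of the 2. At 6 h cbhB lay at -0.14 and 6.56, and its saturated signal at 24 h gave 6.84 and 7.21.

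After 12 h the same comparison with fructose gave high ratios with close replicates. The log2 ratio of xyrA was 8.47 ± 0.10 (SD, n = 2; adjusted p = 0.00235 in limma), that of xynB 7.25 ± 0.09, of aguA 6.21 ± 0.12 and of aceA 5.87 ± 0.22. Of the xylan hydrolase genes 6 of 9 were called higher, and 8 when adjusted over the list alone (camera adjusted p = 3.99e-06, and adjusted p = 0.539 with an estimated correlation); faeA was at 5.22 and An15g04550, entered as a family 11 xylanase, at 4.25. All 4 pentose catabolism genes were called higher, also when adjusted over the list alone (camera adjusted p = 1e-04, and adjusted p = 0.539 with an estimated correlation). Of the arabinose- and galactose-releasing enzymes 4 of 7 were called higher, and 5 when adjusted over the list alone (camera adjusted p = 0.000507, and adjusted p = 0.539 with an estimated correlation), with abfB at 6.05 and abfA at 1.78. The cellulase list kept 1 called gene, bgl1 at 3.64, and 2 when adjusted over the list alone (camera adjusted p = 0.00505, and adjusted p = 0.616 with an estimated correlation). The pentose phosphate list had 1 of 4 genes called higher, gsdA for glucose-6-phosphate dehydrogenase at 0.58, and 4 when adjusted over the list alone (camera adjusted p = 0.00595, and adjusted p = 0.539 with an estimated correlation). This call was lost with median centring (adjusted p = 0.237) and the authors' table (0.0849), and that of the cellulases with fry's directional test (0.0653).

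Outside sugar use, the nitrate reductase gene niaD was higher at 12 h by 2.32 (SE 0.38, adjusted p = 0.0319). Genes with a symbol that fell were Tan1 (-1.17), the protease gene pepC (-0.97), cprA (-0.78), pgaA (-0.68), nsfA (-0.67), dapB (-0.54) and EPR (-0.54); goxC was not well above background on xylan and at least 1.36-fold lower. The autophagy and chitin list was not called at 12 h (camera adjusted p = 0.108). Its median was -0.40 in replicate 1 and -0.51 in replicate 2. The loci with the largest falls, picked after their values were seen, were An07g06240 (-4.86) and An13g02980 (-4.66). In all 1794 of 14050 genes were called, 660 higher and 1134 lower, 595 of them at least 2-fold. The count was 4229 without either 6 h array or without both, 0 without either 12 h array, 512 without either 24 h array, 113 with slide as a random block and 4961 with array weights. The higher share was 36.8%, 25.2% with median centring, 19.5% with slide as a random block and 48.5% with the authors' table.

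After 24 h cellulase and pectinase genes were called beside the xylan genes. The cellobiohydrolase gene cbhB was saturated on xylan and at least 130.2-fold higher than on fructose (adjusted p = 0.0305 in limma). Its difference from 12 h did not pass the test (adjusted p = 0.617 in limma). The spread used there takes in the 6 h replicates, at -0.14 and 6.56, so the result does not show that cbhB stayed level. The endoglucanase genes eglB (An07g08950) and eglA were higher than on fructose by 6.46 (SE 0.91, adjusted p = 0.00818) and 6.39 (SE 0.96, adjusted p = 0.0097). An07g08950 has the symbol eglB in the gene table but was entered in the list as eglC. The locus entered as eglB was An16g06800. Of the cellulase and beta-glucosidase genes 5 of 7 were called higher and 1 lower, An16g06800 at -1.52; adjusted over the list alone 6 were higher and 1 lower, and the list itself was not called (camera adjusted p = 0.0704, and adjusted p = 0.779 with an estimated correlation), but had an adjusted p of 0.00325 without either 6 h array. Of the xylan hydrolases 8 of 9 were called higher, also when adjusted over the list alone (camera adjusted p = 0.000565, and adjusted p = 0.714 with an estimated correlation). Of these, xynB and aceA were saturated and at least 236-fold and 169.5-fold higher, aguA was at 7.43 ± 0.24 (SD, n = 2), xlnD at 5.26 ± 0.14, and axhA, xynA and faeA at 5.18, 4.98 and 5.85. The remaining locus, An14g07390, entered in the list as xynA, was at 0.04 (adjusted p = 0.71 in limma). The symbol xynA stands here for An03g00940, which was entered as xlnC. In pentose catabolism 3 of 4 genes were called higher, and 4 when adjusted over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.714 with an estimated correlation), with xyrA at 8.22 ± 0.20. Of the arabinose- and galactose-releasing enzymes 5 of 7 were called higher, and 6 when adjusted over the list alone (camera adjusted p = 0.00968, and adjusted p = 0.714 with an estimated correlation). The alpha-galactosidase gene aglB was saturated and at least 59.7-fold higher, aglA was at 3.03, and abfA was at 0.14 (adjusted p = 0.686).

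Of the pectinases at 24 h 7 of 12 were called higher and 1 lower, and 7 and 2 when adjusted over the list alone; the list itself was not called (camera adjusted p = 0.106, and adjusted p = 0.714 with an estimated correlation). An03g06740 and An12g07500, entered as exopolygalacturonases, were at 4.86 and 4.42, and the rhamnogalacturonan acetylesterase gene rgaeA, outside the lists, at 7.61 (SE 1.29, adjusted p = 0.0136). The xylanase regulator gene xlnR was higher by 2.42 (SE 0.15, adjusted p = 0.00111). Other lists held called members without a list call. In autophagy and chitin degradation 3 of 5 genes were higher and 1 lower (camera adjusted p = 0.224, and adjusted p = 0.714 with an estimated correlation), with An09g02240, entered as N-acetylglucosaminidase, at 2.58 and An02g07020, entered as chitinase, at 2.14. In the pentose phosphate pathway 3 of 4 were lower (camera adjusted p = 0.0911, and adjusted p = 0.714 with an estimated correlation), with the transketolase locus An08g06570 at -1.26. In the list of secretory stress and protein folding 1 of 6 was lower and 0 when adjusted over the list alone (camera adjusted p = 0.106, and adjusted p = 0.779 with an estimated correlation), pdiA for protein disulfide isomerase at -0.67.

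Among genes with a symbol the largest falls at 24 h were those of catR (-4.44), a catalase gene, niaD (-2.90), aphA (-2.12) and the NADP-dependent glutamate dehydrogenase gene gdhA (-2.04). They were followed by cprA (-1.88), the alternative oxidase gene aox1 (-1.79), the ornithine carbamoyltransferase gene argB (-1.78) and leu2A (-1.69). The fructose signal of the phosphofructokinase gene pfkA and of adhA was saturated, so that these were at least 3.45-fold and 3.22-fold lower on xylan. A second isopropylmalate dehydrogenase gene, leu2B, was higher by 6.12 (SE 0.27, adjusted p = 0.000643). The glycolysis genes gpdA (-1.33), GlkA (-1.23) and hxk (-0.63) did not pass the test. Loci outside the rule, picked after their values were seen, were An07g08940 (8.28), An13g02980 (-5.08) and An02g03200 (-4.98). In all 5035 of 14051 genes were called, 2680 higher and 2355 lower, 2382 of them at least 2-fold. Without 24 h replicate 1 the count was 2151, without 24 h replicate 2 1915, and with slide as a random block 2542. The higher share was 53.2%, but lower with other scalings: 43.6% with median centring, 45.4% with the scanner's log ratio and 46% with the authors' table.

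The gluconeogenesis and glyoxylate list, called at 6 h, was not called at 12 h (0 of 5 genes called, camera adjusted p = 0.866). At 24 h it had 1 gene higher and 1 lower (camera adjusted p = 0.678). Pectinases at 12 h had 0 genes higher and 1 lower (camera adjusted p = 0.866). The sugar transporter locus An12g07450 was at 0.10 at 12 h and 1.32 at 24 h. The remaining fixed lists had few calls against fructose. Starch-degrading enzymes had 1, 0 and 1 of 4 genes called higher at 6, 12 and 24 h (camera adjusted p = 0.0699, 0.866 and 0.534), and the glucoamylase gene glaA was at 1.19 at 24 h without passing the test. Of the inulin and sucrose enzymes the invertase gene suc1 was called, at 24 h (2.30 (SE 0.21, adjusted p = 0.00269); list camera adjusted p = 0.678, and adjusted p = 0.832 with an estimated correlation). In conidiation and spore pigment An09g05730, entered as a pigment polyketide synthase, was lower at 12 h (-1.20) and 24 h (-0.93), and An01g10540, entered as the regulator brlA, was higher at 24 h (0.58; list camera adjusted p = 0.762). Of the secreted proteases pepF was lower at 24 h (-0.98); the list's median was 1.00, its mean 0.61 and its camera direction down (adjusted p = 0.996). None of the 3 glycolysis loci tested was called at any time (camera adjusted p = 0.777, 0.866 and 0.268). The phosphofructokinase gene pfkA, called lower at 24 h, was not among these loci. Of the regulators, xlnR was also called at 6 h (0.89) and amyR was lower at 24 h (-0.58; list median -0.26, mean 0.21, camera adjusted p = 0.755). The mannan loci, too few for a list test, were mndA, higher at 6 h (0.79) and 12 h (0.78), and An05g01320, lower at 12 h (-1.40). In the mannitol list, also too small to test, An03g02430 was called lower at 6 h (-1.92), 12 h (-1.56) and 24 h (-2.19).

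**Figure D3:**
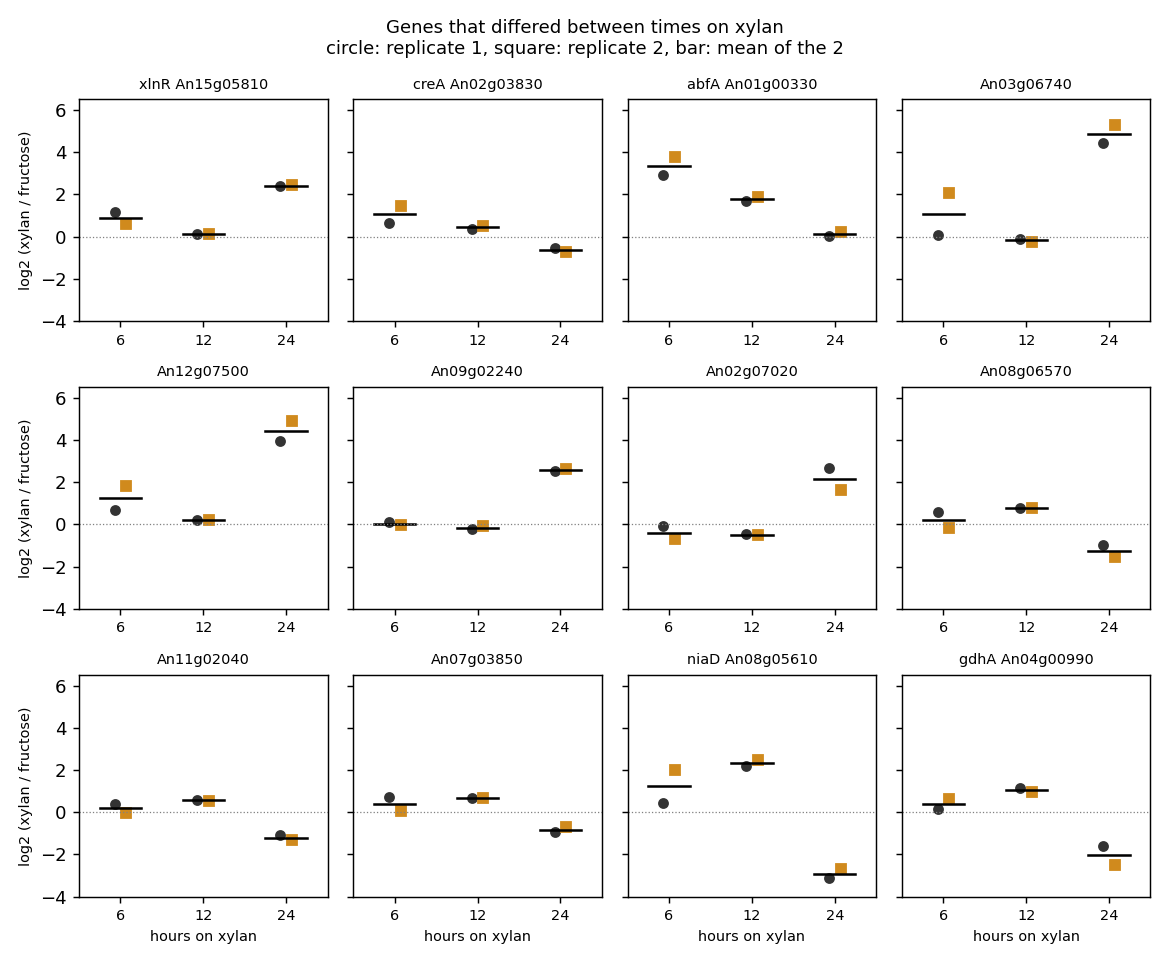
Each panel shows 1 gene, with hours on xylan on the horizontal axis and log2 of xylan over fructose on the vertical axis; circles are replicate 1, squares replicate 2 and bars the mean of the 2. The niaD mean was 2.32 at 12 h and -2.90 at 24 h, and the xlnR mean 0.12 and 2.42.

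The next question was how expression differed between times on xylan. From 12 h to 24 h, on arrays of 1 slide, the pentose phosphate genes fell: 3 of 4 were called lower and 4 when adjusted over the list alone (camera adjusted p = 0.0023, and adjusted p = 0.731 with an estimated correlation). An08g06570, entered as transketolase, fell by 2.06 on the log2 scale. An11g02040, entered as 6-phosphogluconate dehydrogenase, was at -1.78 and An07g03850, entered as transaldolase, at -1.49. In autophagy and chitin degradation 3 of 5 genes rose, also when adjusted over the list alone (camera adjusted p = 0.0354, and adjusted p = 0.731 with an estimated correlation): An09g02240 by 2.72 (SE 0.11, adjusted p = 0.00194), An02g07020 by 2.62 and An07g10020, entered as atg8, by 1.05. Of the pectinases 3 of 12 rose; adjusted over the list alone 6 were higher and 1 lower, with An03g06740 up by 5.04 and An12g07500 by 4.20; the list was not called (camera adjusted p = 0.247, and adjusted p = 0.783 with an estimated correlation). The gene xlnR rose by 2.30 (SE 0.21, adjusted p = 0.00863). The call of the autophagy and chitin degradation list held in 14 of 23 settings. With the replicate number as a block the call was lost (camera adjusted p = 0.0507). Among other settings, it was lost with probes well above background alone (adjusted p = 0.0526), array weights (0.0603) and a trend and robust prior (0.066). The same held with Agilent's processed signals (0.0536), its log ratio (0.0945), the authors' table (0.0562) and without 12 h replicate 1 (0.0946). Leaving out 6 h replicate 1, the xylan hydrolases (camera adjusted p = 0.00917) and cellulases (0.0214) were called higher and glycolysis (0.0325) lower, with values of 0.00914, 0.0213 and 0.0324 without 6 h replicate 2.

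Between 12 h and 24 h niaD fell by 5.22 on the log2 scale (SE 0.54, adjusted p = 0.0107), while leu2B rose by 4.63. Also lower were gdhA (-3.11), leu2A (-2.21), abfA (-1.64) and cprA (-1.10). Also higher were dhbD (3.78), hyl1 (3.30) and Sox (2.54). The polygalacturonase gene pgaC was not well above background at 12 h; its Cy5 signal alone was at least 32-fold higher at 24 h, and the ratio differed by 4.32 on the log2 scale. Loci outside the rule, picked after their values were seen, were An07g03470 (7.07), An05g01730 (6.82) and An08g05670 (-6.22). In all 1856 genes were called, 1312 higher and 544 lower. The arrays of this slide alone, which is also the fit without either 6 h array, called 3920, and slide as a random block 3020; without either 12 h array the count was 43, without 24 h replicate 1 525 and without 24 h replicate 2 303. The higher share was 70.7%, 58.1% with the scanner's log ratio and 57.2% with the authors' table.

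Between 6 h and 24 h the pentose phosphate list was called lower again, with 3 of 4 genes, and 4 when adjusted over the list alone (camera adjusted p = 0.0118, and adjusted p = 0.919 with an estimated correlation). The call was lost with the scanner's log ratio (adjusted p = 0.0583) and the authors' table (0.0508). The gene abfA fell by 3.20 on the log2 scale (SE 0.30, adjusted p = 0.00801). Also lower were niaD (-4.13), the pyruvate carboxylase gene pyc (-3.33), pgaB (-2.56), gdhA (-2.43), leu2A (-1.97) and the carbon repressor gene creA (-1.71). Higher were leu2B (5.29), pgaC (3.95, above background on 1 of 2 arrays at 6 h), dhbD (3.63), hyl1 (3.47), aglA (3.33) and suc1 (2.61). Loci outside the rule, picked after their values were seen, were An01g06890 (8.76), An01g06860 (8.66), An08g05670 (-4.65) and An11g07340 (-4.40). In all 2081 genes were called, 1444 higher and 637 lower. Time cannot be told apart from slide and scan here, since the 6 h arrays lay on slides of their own; slide as a random block called 599, array weights 1291 and a fit to these groups alone 694. Without 6 h replicate 1 the count was 4083, without 6 h replicate 2 3403, without either 12 h array 694, and without 24 h replicate 1 or 2 633 or 463. The higher share was 69.4%, 55.4% with the scanner's log ratio and 54.9% with the authors' table. The list medians of replicates 1 and 2 at 6 h were 1.73 and 5.27 for the xylan hydrolases and 0.20 and 4.74 for the cellulases. Glycolysis had 1.02 and -1.04, and secretory stress 0.00 and 1.34. At 24 h the 4 lists had 5.16 and 5.36, 4.80 and 5.24, -1.36 and -1.10, and -0.85 and -0.39. Counts and list tests without a 6 h array rest on 1 array there and hold no spread between the 6 h replicates.

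Between 6 h and 12 h few single genes were called. Gluconeogenesis and glyoxylate genes were lower as a list, with 0 of 5 members called over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.000853, and adjusted p = 0.478 with an estimated correlation; median -1.32). Pectinases were lower as a list, with 0 members called either way (camera adjusted p = 0.000853, and adjusted p = 0.478 with an estimated correlation; median -0.38), and regulators likewise (camera adjusted p = 0.0371, and adjusted p = 0.478 with an estimated correlation; median -0.26). By fry's directional test the adjusted p values of the 3 lists were 0.18, 0.122 and 0.0847. In all 7 genes were called, 4 higher and 3 lower, none with a symbol, and 1310 had an unadjusted p under 0.05 in limma. Picked after their values were seen, the higher genes were An01g14550 (2.91), An14g05840 (2.58), An09g00620 (2.51) and An08g10010 (1.48). The lower genes were An10g00170 (-1.29), Aspni5_42502_fge... (-2.39) and An14g02170 (-3.99). The last was not well above background at 12 h, and its Cy5 signal alone was at least 29.5-fold lower. The count was 674 without 6 h replicate 1, 759 without 6 h replicate 2, 0 without any 1 of the other arrays, and 0 with slide as a random block. With the replicate number as a block the count was 0 too. The regulator list was called in 6 of 22 settings, and not with this block (camera adjusted p = 0.0556). Its adjusted p was 0.155 with Agilent's processed signals, 0.181 with its log ratio, 0.168 with the authors' table, 0.0584 without background correction, 0.0855 with a trend and robust prior, 0.0634 in a fit to these groups and 0.144 with the Cy5 signal alone. It had adjusted p values of 0.0601 without 6 h replicate 1, 0.0873 and 0.0623 without 12 h replicate 1 or 2, and 0.0635 and 0.0633 without 24 h replicate 1 or 2. The cellulase median was 0.20 and 4.74 on the 6 h arrays, and 1.80 and 1.84 on the 12 h arrays. That of the xylan hydrolases was 1.73 and 5.27 at 6 h, and 4.71 and 4.73 at 12 h. The direction of the cellulases thus depends on the 6 h replicate. Counts and list tests without a 6 h array rest on 1 array there and hold no spread between the 6 h replicates. Time cannot be told apart from slide and scan in this comparison.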

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

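All tests of explanations in this part were chosen after the result was seen. Differences between times, which are differences between the times' responses against fructose, were tested in limma for each gene and in camera for each list. Between 6 h and 12 h 7 genes passed, between 12 h and 24 h 1856, and between 6 h and 24 h 2081. Lists that differed from 6 h to 12 h were pectinases (camera adjusted p = 0.000853), gluconeogenesis and glyoxylate cycle (0.000853) and regulators (0.0371). From 12 h to 24 h they were the pentose phosphate pathway (0.0023) and autophagy and chitin degradation (0.0354), and from 6 h to 24 h the pentose phosphate pathway (0.0118). With an estimated correlation the adjusted p of each lay between 0.478 and 0.919.

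Only named genes called in the comparison at hand are given in this paragraph. Those with a higher log2 ratio at 12 h than at 6 h were An01g14550 (2.91), An14g05840 (2.58), An09g00620 (2.51) and An08g10010 (1.48). Those called with a lower ratio were An10g00170 (-1.29), Aspni5_42502_fge... (-2.39) and An14g02170 (-3.99). From 12 h to 24 h the difference was above 0 for leu2B (4.63), pgaC (4.32), dhbD (3.78), hyl1 (3.30), Sox (2.54), xlnR (2.30), An07g03470 (7.07), An05g01730 (6.82) and An03g06740 (5.04). It was also above 0 for An12g07500 (4.20), An09g02240 (2.72), An02g07020 (2.62), suc1 (2.19), bgl1 (1.39), An12g07450 (1.23), An07g10020 (1.05), An01g10930 (0.94) and rhgA (0.89). From 12 h to 24 h the difference was below 0 for cprA (-1.10), adhA (-1.63), abfA (-1.64), leu2A (-2.21), gdhA (-3.11), niaD (-5.22), An08g05670 (-6.22), mndA (-0.89) and An07g03850 (-1.49). It was also below 0 for An11g02040 (-1.78), An16g06800 (-2.01) and An08g06570 (-2.06). The Cy3 signal of adhA was saturated at 24 h, and pgaC and An14g02170 were not well above background at 12 h. From 6 h to 24 h the higher genes were leu2B (5.29), pgaC (3.95), dhbD (3.63), hyl1 (3.47), aglA (3.33), suc1 (2.61), An01g06890 (8.76), An01g06860 (8.66) and An03g06740 (3.78). The other genes called higher were An12g07500 (3.17), An09g02240 (2.55), An02g07020 (2.54), xlnR (1.53) and rhgA (0.85). From 6 h to 24 h the lower genes were leu2A (-1.97), gdhA (-2.43), pgaB (-2.56), abfA (-3.20), pyc (-3.33), niaD (-4.13), An11g07340 (-4.40), An08g05670 (-4.65) and gsdA (-0.71). The other lower genes were mndA (-0.90), pelB (-1.05), An02g05830 (-1.19), An07g03850 (-1.21), An11g02040 (-1.41), An16g06800 (-1.45), pmeA (-1.63), creA (-1.71) and An15g01860 (-1.85).

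The 6 h arrays lay farther apart than the other replicate pairs, with a correlation over genes of 0.42 against 0.90 and 0.96. A different control RNA would put the difference in Cy3, but the variance of the replicate difference in Cy3 was 0.297 times that in Cy5. The SD of that difference over genes was 0.75, 0.21 and 0.29 in Cy5 at 6, 12 and 24 h. In Cy3 it was 0.41, 0.28 and 0.27, so Cy3 was wider at 6 h as well, and a smaller part from the control stays open. A swap with a 12 h or 24 h array would leave a partner out of place, but the lower correlation of those pairs was 0.896, and compressed ratios on replicate 1 are argued against by a spike-in slope 1.00 times that of replicate 2. A less advanced response in replicate 1 would make the difference of replicate 2 minus 1 correlate positively, over genes, with the 12 h ratios. The value was 0.408. Any other cause that left replicate 1 less like the 12 h arrays would also give a positive value, so it cannot favour this explanation. A less advanced response stays open as a hypothesis together with an outside mix-up. List medians were mixed on a less advanced replicate 1. That of the xylan hydrolases was 1.73 and 5.27 at 6 h and 4.71 and 4.73 at 12 h, with replicate 2 nearer to 12 h. That of the cellulases was 0.20 and 4.74 at 6 h and 1.80 and 1.84 at 12 h, with replicate 1 nearer. Culture and slide cannot be told apart, since 0 slides held a 6 h array and another array.

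Replicates 1 and 2 differed alike at every time in Cy3, the fructose channel. Over genes, the Cy3 replicate differences correlated at 0.485 between 6 h and 12 h, which share no slide or scan, which argues against slide or scan as the cause. The lowest Cy3 correlation between times was 0.459, while the Cy5 values were -0.00321, -0.0776 and -0.0153. A candidate explanation is a separate fructose RNA for each replicate number. The labels do not say how many fructose cultures were used, and no other biological explanation was tested.

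On the slide with the 12 h and 24 h arrays, Cy3 rose for many genes whose Cy5 signal rose strongly and whose Cy3 signal was dim. This held for 85.7% of 91 such genes in replicate 1 and 80% of 115 in replicate 2, with median Cy3 changes of 0.60 and 0.48 on the log2 scale. A fixed share of Cy5 light read in Cy3 could raise nearly every such gene and cannot be told apart from a change of the control RNA or of the normalization, since the shares lie between the limits set for either outcome. If present, it could make ratios of strongly induced genes too small.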

How the results depend on the processing

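Both 6 h arrays left out, and the Cy5 signal alone, were the alternatives chosen only after the data were seen. Over all alternatives, named genes kept direction and side of the threshold in 9370 of 11129 values, lost the call in 846, gained it in 640, changed sign without a call in 269 and with one in 4. For lists 1755 of 1974 values did not change in this sense, 53 lost and 101 gained the call, 61 changed direction without a call and 4 with one. Both totals include Aquantile scaling, which left all 586 named-gene values the same, and settings that repeat one another. They also count results uncalled in both fits as unchanged. Only called genes can lose a call, so the 846 losses are not a share of all 11129 values. The cause of the changes below was not tested, except that a lone array, fewer arrays or a fold threshold change what is tested.

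Called genes of at least 2-fold numbered 423 at 6 h, 595 at 12 h and 2382 at 24 h against fructose, 1147 from 12 h to 24 h and 1313 from 6 h to 24 h. Slide as a random block (correlation 0.591) called 405, 113 and 2542 genes at 6, 12 and 24 h, 0 from 6 h to 12 h, 3020 from 12 h to 24 h and 599 from 6 h to 24 h. Array weights called 109 at 6 h, 4961 at 12 h, 3 from 6 h to 12 h, 3728 from 12 h to 24 h and 1291 from 6 h to 24 h. A fit to the groups compared called 0 at 6 h, 4365 at 12 h, 0 from 6 h to 12 h, 3920 from 12 h to 24 h and 694 from 6 h to 24 h. Without both 6 h arrays the counts were 4229 at 12 h and 3920 from 12 h to 24 h.

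Median centring called 1977 genes at 6 h and 2951 at 12 h, and 3209 genes were called at 12 h with the authors' table. That table's median over all genes was 0.10 at 12 h, -0.17 from 12 h to 24 h and -0.16 from 6 h to 24 h. From 6 h to 12 h the count was 0 with Agilent's processed signals, 0 with its log ratio, 0 with the authors' table, 12 without background correction, 3 with median centring, 4 with a trend and robust prior and 103 with the Cy5 signal alone. With the replicate number as a block limma called 1206, 1826 and 5095 genes at 6, 12 and 24 h, 0 from 6 h to 12 h, 1807 from 12 h to 24 h and 2081 from 6 h to 24 h, and 1 list from 12 h to 24 h, the pentose phosphate pathway, with adjusted p values of 0.0507 for autophagy and chitin degradation and 0.0556 for the regulators from 6 h to 12 h. Replicate differences of the log2 ratio correlated over genes at 0.347 (6 h and 12 h), 0.192 (6 h and 24 h) and 0.536 (12 h and 24 h). Those of the Cy3 signal alone correlated at 0.485, 0.459 and 0.626 in the same order, as a separate fructose RNA for each number could give. The labels name no culture or day that a number stands for, and 2 numbers are too few to settle from these values whether they pair the arrays. The fit without the block was kept, so calls that were lost with the block are open to such pairing.

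With an estimated correlation, tested on 3 residual degrees of freedom, 0 lists were called in every comparison. By fry's directional test 9 lists were called at 24 h, 0 from 6 h to 12 h, 5 from 12 h to 24 h and 4 from 6 h to 24 h. By its mixed test the numbers were 12 at 6 h, 13 at 24 h, 0 from 6 h to 12 h, 9 from 12 h to 24 h and 10 from 6 h to 24 h. Median centring called 6 lists at 24 h and 2 from 6 h to 24 h, and a fit to the groups compared 5 at 24 h and 5 from 12 h to 24 h, as without both 6 h arrays (5). From 12 h to 24 h 1 list was called with Agilent's processed signals, its log ratio, the authors' table, probes well above background alone, array weights, and a trend and robust prior. From 6 h to 24 h 0 lists were called with the log ratio and the authors' table, and 3 with array weights.

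With each array left out in turn the gene counts ranged over 170 to 3993 at 6 h, 0 to 4229 at 12 h, 1915 to 6609 at 24 h, 0 to 759 from 6 h to 12 h, 43 to 3920 from 12 h to 24 h and 463 to 4083 from 6 h to 24 h. List calls ranged over 6 to 9, 5 to 6, 3 to 4, 2 to 8, 1 to 5 and 1 to 4 in the same order. Of 31, 32 and 64 named genes called at 6, 12 and 24 h, 12, 0 and 25 were still called at the lowest when 1 array was left out. Values that changed direction in a call ranged from -0.77 (without 6 h replicate 1) to 1.38 (without 6 h replicate 2) for GlkA at 6 h, -0.91 to 2.90 for axhA from 6 h to 12 h, and -1.41 to 3.33 for cbhA from 6 h to 24 h, each with the same arrays left out. For gpdA at 6 h the range was -1.04 (without replicate 1) to 1.02 (without replicate 2). Without 6 h replicate 2 the glycolysis list at 6 h was higher (adjusted p = 0.0374) and without replicate 1 lower (adjusted p = 0.0262), with adjusted p up to 0.791 without another array. Likewise the cellulase list from 6 h to 12 h was higher without 6 h replicate 2 (adjusted p = 0.0113) and lower without replicate 1 (adjusted p = 0.00164), with adjusted p up to 0.986. The regulator list was higher by fry at 24 h (adjusted p = 0.012) and from 12 h to 24 h (0.035).

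Aquantile scaling left every ratio as it was, and the brightest probe was not run because each gene has 1 probe. A fold threshold for lists and word members were not run. Slide as a fixed term was possible for 12 h against 24 h alone, where it equals the fit to those groups. Signal over background limits dim genes, with 70.3% to 77.5% of genes well above background in Cy5.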

Other observations

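The tests in this part were chosen after the result was seen. Genes with high ratios after 24 h on xylan included runs of neighbours. The longest run of genes at least 8-fold higher than on fructose held 10 adjacent genes, from An01g06810 to An01g06900, with log2 ratios from 3.27 to 5.45 at 24 h and a median of 4.31. The median of these genes was -3.07 and -1.62 on the 6 h arrays and 1.86 at 12 h. A run of 4 genes, An16g05910 to An16g05940, had a median of 3.33 at 24 h, 1.74 at 12 h, and -2.45 and 0.59 on the 6 h arrays. All passed the test at 24 h in limma except An01g06820 (adjusted p = 0.0502) and An16g05910 (adjusted p = 0.0514), and none has a symbol in the gene table.

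The hypothesis that neighbouring genes share their change was tested with the gene order of the RefSeq table. Over 13874 adjacent pairs the 24 h log2 ratios correlated at 0.0915 (permutation p = 1e-04), a value that holds the runs that prompted the test; the longest run in 1000 shuffles was 4 genes. Without the 14 run members the correlation was 0.0795, and the highest in 10000 shuffled orders 0.0409 (one-sided permutation p = 1e-04, the smallest that so many shuffles can give). Without all 347 genes at least 8-fold higher it was 0.0568, with a highest shuffled value of 0.0322, which is consistent with a weak shared change of neighbours outside the runs. Probes that cross-hybridise between tandem copies could give the same result; probes of identical sequence were left out, and more distant copies were not tested.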
